A study of Danio rerio with 8 samples.

How the data were processed

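Larvae of 4 control pools (0 ppb) and 4 TCE pools (10 ppb), 50 larvae each, were profiled on single-colour Agilent arrays, 1 array per pool. Groups and replicate numbers were taken from the sample titles, which give both dose and replicate. Per the labels' protocols, embryos were dosed from 1 to 72 hpf, total RNA was isolated on columns and Cy3-labelled cRNA was hybridised. Scans were read with Agilent Feature Extraction 11.5, per the submitters' processing notes.

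The scanner output holds, per the file headers, a processed intensity for each of 180880 spots of an array on a linear scale, with the local background, a call of well above background and outlier flags. A value table made by the authors holds 1 log2 value for each of 128291 probes and array. Its columns have a 75th percentile of 0 and medians between -3.30 and -3.16, and 97.0% to 99.8% of an array's probes lay within 0.01 of a constant offset from the log2 intensities computed here. Its scale is therefore log2 and its centring the 75th percentile. The set of spots behind that percentile stays unknown. The authors' deposited table gives a log2 change and a p-value for 851 probes. The test behind it is not given in the sources used here, and its criteria were recovered by recomputation from the value table. The gene symbols in the authors' deposited table are other values of that file and were used as written.

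From the scanner output, the intensity was set to at least 1, taken to log2 and reduced by the array's 75th percentile. Control spots (4854 per array) were left out, outlier-flagged spots were treated as missing (0.633% of probe values), and spots of one probe were averaged. Probes well above background on at least 4 of the 8 arrays were kept, 88631 of 128291. A probe was named through the accession in its target column, matched without version to RefSeq gene records of the assembly GRCz12tu. Of the probes 39952 had 1 symbol (13547 genes) and 88339 had no symbol here, 19999 of these with an Ensembl transcript identifier for which no table of names was used. Positions in the genome are not given, since the build behind the array design was not matched. Probes of one gene or one unnamed target were averaged after missing probe values had been filled from an additive probe and array fit, which gave 54832 targets. Of these, 54741 had at least 3 values in each group and were tested, 12806 of them named. Values are log2 intensities relative to the array's 75th percentile, so the level of one gene is not comparable with that of another.

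Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), with Benjamini-Hochberg adjustment and a threshold of 0.05, and log2 differences are TCE minus control. Before the data were examined, 34 gene lists were fixed, 17 of pathways and 17 of cell types, with 1396 distinct symbols, of which 1144 were measured. Lists were tested with camera (preset inter-gene correlation 0.01), camera with an estimated correlation and fry, after 2463 missing gene values had been filled from flagged spots, and each median was placed among 10000 random lists matched on signal. A list's score on an array is the mean deviation of its members, and scores were compared by two-sided exact permutation over 70 assignments, whose smallest p is 0.0286. These assignments ignored the replicate number and the slide of an array. Exchanges within pairs of equal number, or within slides, are fewer and could not give so small a p. That a p covers the spread between pools rests on the submitters' statement that pools are biological replicates.

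Genes were named by a rule fixed at the same time as the lists. It takes up to 10 genes per direction with the smallest p, filled up with genes that did not pass, up to 2 members per list with the smallest p, the 5 largest changes in each direction of the authors' deposited table, and the largest difference in each direction among genes above background on all 8 arrays. Placeholder symbols were counted and not named, and some genes that the rule takes are not reported here and were not replaced.

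Whether the replicate numbers pair the pools was checked from the deviations of each array from its group mean. The 4 pairs with the same number had correlations between 0.155 and 0.304, all over 0.1, against -0.006 to 0.187 for other numbers on the same slide and -0.222 to -0.080 across slides. On slide 2 the pools of different number, at 0.165 and 0.187, correlated no less than those of the same number, at 0.155 and 0.161, so there the number adds nothing to the slide. As all 4 pairs were over 0.1, the numbers were taken to pair the pools, and the fit with the number as a block is given beside a result where it changes a call. Slides were read from the scanner headers. Controls lay at positions 1 and 3 of each slide and TCE pools at positions 2 and 4, so position and group cannot be told apart. Pools of equal number also held consecutive positions of a slide, and the labels state no pairing. The scan date followed the slide and was not run separately.

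On simulated data with the real means and SDs of 54832 targets, 4 arrays against 4, limma recovered a median of 34.3% of genes planted at 1.5-fold over 100 draws (20.9% to 52.2%), 64.2% at 2-fold (49.3% to 77.6%) and 92.4% at 4-fold (78.8% to 97.0%). It called 0 to 14 of 54632 unchanged genes. In a single draw camera with the preset correlation found 5 of 5 lists planted with a shift of 0.1 and called no other list. When the members of each unshifted list shared noise with an SD of 0.07, it called 3 to 20 of 34 lists over 100 draws (median 12), while camera with an estimated correlation and fry each called 0 to 1. That SD was chosen, not estimated from the arrays. Camera with an estimated correlation and fry were not run on lists with a planted shift, so their power was not measured.

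Alternatives were quantile normalization, median centring, normexp background correction (offset 50), no filter, a filter on all 8 arrays, the brightest probe per gene, the replicate number and the slide as blocks, the authors' value table, other variance models, flagged spots kept, other list tests and leaving out each array. Normexp was planned on mean spot signals and ran on median spot signals, since the scanner output used here gives the latter. A refit to named genes alone, adjusted over them, and the comparison within each slide were added after seeing the data.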

Results

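Gene expression was measured in whole zebrafish larvae of the AB strain at 72 hours post fertilization (hpf). Embryos were kept from 1 to 72 hpf in water with 0 ppb (control) or 10 ppb of trichloroethylene (TCE), a chlorinated solvent. Each sample was RNA from a pool of 50 larvae, with 4 control pools and 4 TCE pools, numbered 1 to 4 in each group and described by the submitters as biological replicates. Each pool was hybridised to one Cy3-labelled Agilent array. The 8 arrays lay on 2 slides with 4 arrays each, pools 1 and 2 of both groups on slide 1 and pools 3 and 4 of both groups on slide 2. The array comparison concerned the lowest dose of a study on heart development, vessel growth, F-actin and mitochondria, and asked which transcripts differed between larvae exposed to that dose and unexposed larvae.

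No difference between the groups was found in 4 quality measures (exact permutation tests, two-sided, p between 0.286 and 0.857; all adjusted p = 0.857). The 75th percentile of processed intensity ranged from 1524 to 1864 units over the 8 arrays, and no spot was saturated. The share of probes well above background was 69.0% ± 3.0 (SD, n = 4) in control and 69.6% ± 1.7 (SD, n = 4) in TCE, with the lowest value, 64.5%, on the array of control pool 3, which stood apart from the other controls. Spots flagged as non-uniform or as outliers made up 0.183% to 4.04% of an array, the highest share being on control pool 1, which also stood apart. Correlations between arrays over all measured genes lay between 0.987 and 0.993 (across genes, which are not independent replicates). The first principal component held 24.5% of the variance and separated the slides. The third held 14.4% and separated the groups, controls lying from 3.25 to 38.5 and TCE pools from -32.6 to -13.9. Its exact permutation test gave p = 0.0286 (two-sided, the smallest that 70 unpaired assignments can give), though none of the 7 components passed after adjustment. The number of arrays limits the precision of each value given here.

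Among named genes, those with the smallest p-values lay in both directions. The transcript of fosab, a Fos family transcription factor induced within minutes of stimulation, averaged -0.64 ± 0.13 (SD, n = 4) log2 units relative to the array's 75th percentile in control and -1.25 ± 0.10 (SD, n = 4) in TCE. Its log2 difference was -0.61 (SE 0.09). The immediate-early gene ier2a differed by -0.41 (SE 0.07), and the hormone gene lepa, which encodes a leptin, by -1.80 (SE 0.29), a 3.49-fold lower mean, and by -1.09 after normexp background correction. On the higher side, lgals1l1, a galectin gene, averaged 2.63 ± 0.19 (SD, n = 4) in control and 3.27 ± 0.16 (SD, n = 4) in TCE, a log2 difference of 0.64 (SE 0.11). A fatty acid-binding protein gene, fabp4b, differed by 0.56 (SE 0.10). These values are those of single genes that did not pass the test across all genes. The value of lepa rests on 1 probe of low signal, which averaged -2.91 ± 0.58 (SD, n = 4) in control and -4.71 ± 0.41 (SD, n = 4) in TCE.

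The other genes with the smallest p in the lower direction were ctslb, which encodes a cathepsin L protease of the hatching gland (log2 difference -0.69, SE 0.12), and cacna1sa, which encodes the pore subunit of the skeletal muscle calcium channel (-0.72, SE 0.14). They were joined by igfbp6b, an insulin-like growth factor binding protein gene (-0.63, SE 0.13), the transporter gene abcc5 (-0.40, SE 0.08), upf3a of nonsense-mediated decay (-0.33, SE 0.06) and the clustered protocadherin genes pcdh2aa15 (-0.33, SE 0.07) and pcdh2aa3 (-0.29, SE 0.06). In the higher direction they were mlec, an endoplasmic reticulum lectin gene (0.43, SE 0.10), ush1c, a hair cell scaffold gene (0.43, SE 0.11, and -0.20 when outlier-marked spots were kept), bora, a cofactor of mitotic kinases (0.39, SE 0.10), hes2.2, a transcriptional repressor gene of the Hes family (0.36, SE 0.09), and gch2, a GTP cyclohydrolase gene of pteridine pigment synthesis (0.29, SE 0.07). The rest of that set was sae1, which encodes a subunit of the SUMO-activating enzyme (0.28, SE 0.07), dut, the dUTPase gene of nucleotide metabolism (0.25, SE 0.05), and samm50 of the mitochondrial outer membrane (0.20, SE 0.05). Each of these 20 genes differed in its stated direction in 4 of 4 pairs of pools with the same replicate number, and within each slide. Selection by p-value favours such an outcome. Of the 20, lepa, fabp4b, cacna1sa, igfbp6b, upf3a, mlec, ush1c and sae1 rest on 1 probe each. The largest positive difference among named genes well above background on all arrays was that of chsy1, a chondroitin synthase gene (0.94, SE 0.66), and it came from TCE pool 2 alone, at 1.32 against a highest value of -1.96 in the other TCE pools. Without that pool the difference was 0.07, and with the brightest probe it was 0.05.

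**Figure D1:**
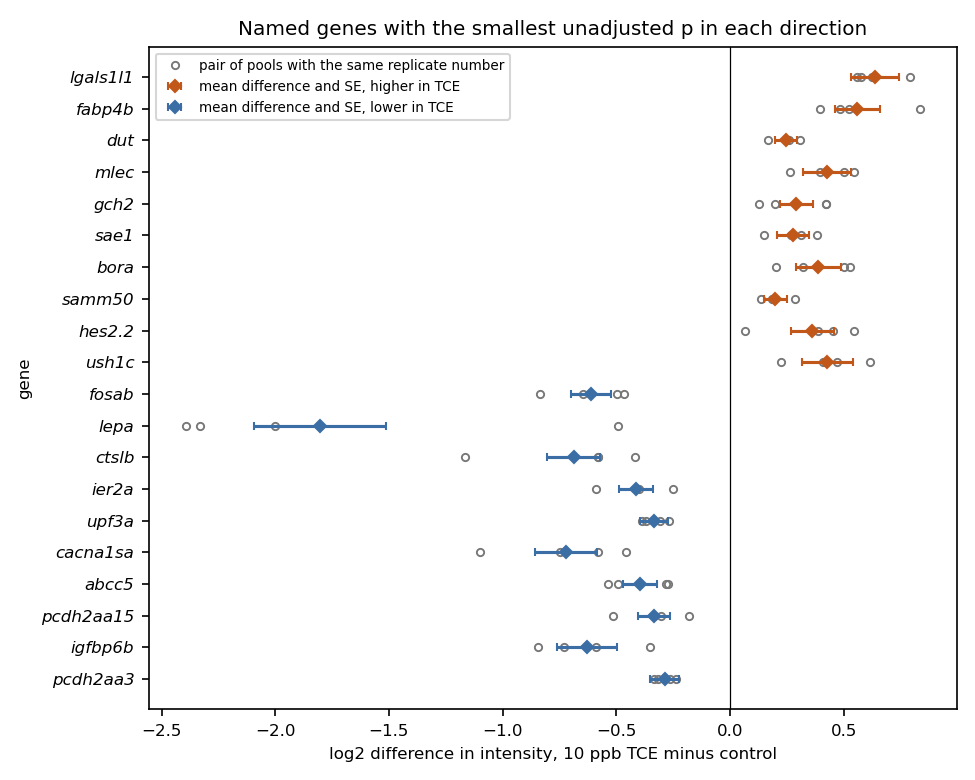
Log2 difference in intensity (horizontal axis, TCE minus control) for the 10 named genes with the smallest unadjusted p in each direction (vertical axis); grey circles are the 4 pairs of pools with the same replicate number, and diamonds with bars are the mean difference and its SE from limma. The circles of each gene lie on one side of 0, lepa has the largest spread, and none of the genes passed the adjusted threshold.

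Across all genes, limma called none of 54741 genes and unnamed targets at an adjusted p of 0.05, the smallest adjusted p being 0.532. At an unadjusted p under 0.05 stood 3079 of them (5.62%), 1557 higher and 1522 lower in TCE, and 820 of these were among the 12806 named genes, 474 higher and 346 lower. The median absolute log2 difference over all targets was 0.09, against a median SE of 0.13. With the replicate number as a block limma called 0 genes (smallest adjusted p = 0.140; 4619 at an unadjusted p under 0.05), and with the slide as a block 0 (0.112; 4011). Within slide 1 alone it called 0 (0.921; 2566), and within slide 2 alone 0 (0.182; 2242). One unnamed target passed when control pool 1 was left out (TC451394, log2 difference -1.30, SE 0.10, limma adjusted p = 0.0199).

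At the level of single probes, those nearest to the threshold included probes of myh9a, a non-muscle myosin heavy chain gene, and of lgals1l1. Of 88401 probes limma called 0 (smallest adjusted p = 0.289), with 5555 at an unadjusted p under 0.05. With the replicate number as a block it called 4, each at an adjusted p of 0.0490 in limma. They were 2 probes of myh9a (both -0.72, SE 0.06), 1 probe of lgals1l1 (0.85, SE 0.07) and 1 probe whose transcript has no name here (-0.74, SE 0.06), and they are named because so few passed, after their values were seen. Without the block the 8 tested probes of myh9a ranged from -0.72 to 0.05, 3 of them at an unadjusted p under 0.05, and the 3 of lgals1l1 from 0.49 to 0.85, all 3 at that level.

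The fixed gene lists that bear on the study's themes moved little and not in one direction. The list of cardiac muscle and heart development genes stood lower in TCE, with 20 of 26 measured members lower (median log2 difference -0.06; camera adjusted p = 0.00811, and adjusted p = 0.659 with an estimated correlation). The call ended with the brightest probe per gene (median -0.03, adjusted p = 0.247), without TCE pool 2 (-0.04, 0.0776) and without TCE pool 4 (-0.03, 0.0739). Its members with the smallest p were desma, the muscle intermediate filament gene desmin (-0.23, SE 0.07), and myh7, a cardiac myosin heavy chain gene (-0.19, SE 0.08; -0.12 without TCE pool 1 and -0.05 when outlier-marked spots were kept). The 71 measured nuclear genes of oxidative phosphorylation stood higher, 65 of them (median 0.07; camera adjusted p = 1.43e-06, and adjusted p = 0.660 with an estimated correlation), with cycsb, a cytochrome c gene, at 0.14 (SE 0.07) and atp5mc3a of the ATP synthase at 0.12 (SE 0.06). Their median was 0.05 without TCE pool 3 and 0.11 without TCE pool 4. Of 37 genes for mitochondrial maintenance, dynamics and import, 31 were higher (median 0.08; camera adjusted p = 1.29e-05, and adjusted p = 0.659 with an estimated correlation), led by the import genes timm10 (0.19, SE 0.06) and tomm22 (0.16, SE 0.05). After quantile normalization the median of this list was 0.05 (camera adjusted p = 0.00669). Its array score was 0.10 in TCE pool 3, while the other TCE pools, at -0.01 to -0.001, lay within the control range of -0.07 to 0.03 (exact permutation test, two-sided, p = 0.286; higher in 3 of 4 pairs). Actin polymerization genes had 28 of 39 members higher (median 0.05; camera adjusted p = 0.0722), with wasla at -0.16 (SE 0.08; -0.03 with the brightest probe) and cdc42 at 0.10 (SE 0.05). Genes of vascular endothelium and angiogenesis had 18 of 30 members lower (median -0.03; camera adjusted p = 0.433), with the Notch ligand gene dll4 at -0.27 (SE 0.07) and angpt2b at 0.26 (SE 0.14), at 0.15 without TCE pool 2 and at 0.06 with the brightest probe. Calcium handling genes had 13 of 24 members higher (median 0.00; camera adjusted p = 0.835), and cacna1sa passed when adjusted over the list alone (adjusted p = 0.00742 in limma), while the calmodulin gene calm2a was at 0.15 (SE 0.06). Such an adjustment was made in each of 34 lists without allowing for their number, and 5 genes in 3 lists passed it.

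Genes of cell cycle and DNA replication had the smallest camera p of the 34 lists. Of 46 measured members, 44 stood higher in TCE, 16 of them at an unadjusted p under 0.05 and none lower at that level (median log2 difference 0.14; camera adjusted p = 1.03e-14, and adjusted p = 0.659 with an estimated correlation). The mean log2 deviation of its members on each array, taken as a score, was -0.06 ± 0.06 (SD, n = 4) in control and 0.06 ± 0.06 (SD, n = 4) in TCE. It was higher in 4 of 4 pairs (exact permutation test, two-sided, p = 0.0286, the smallest that 70 unpaired assignments can give, and 0.324 adjusted over the lists). The pairs differed in size. Control against TCE, the score was -0.118 and 0.122 for pools 1 and -0.110 and 0.096 for pools 4. It was -0.015 and 0.010 for pools 2 and -0.006 and 0.021 for pools 3. The dUTPase gene dut passed when adjusted over the list alone (adjusted p = 0.0141 in limma). The gene of a DNA polymerase alpha subunit, pola2, differed by 0.21 (SE 0.06), and by 0.12 when outlier-marked spots were kept. Cytosolic ribosomal protein genes stood higher in 70 of 71 cases (median 0.09; camera adjusted p = 1.51e-12, and adjusted p = 0.659 with an estimated correlation), with rpl35 and rps27.1 each at 0.15 (SE 0.06). Their array score was higher in 3 of 4 pairs (exact permutation test, two-sided, p = 0.143), at -0.09 in TCE pool 4 against -0.01 in control pool 4. Lens crystallin genes were higher in 31 of 39 cases (median 0.10; camera adjusted p = 4.82e-05, and adjusted p = 0.659 with an estimated correlation), among them crygm2d6 (0.23, SE 0.08) and crygm2d1 (0.14, SE 0.06). Skeletal muscle genes were higher in 26 of 32 cases (median 0.06, and -0.01 after quantile normalization; camera adjusted p = 0.0205, and adjusted p = 0.675 with an estimated correlation), as were 26 of 37 genes of the oxidative stress response (median 0.05; camera adjusted p = 0.0328, and adjusted p = 0.660 with an estimated correlation). Their leading members were the skeletal actin gene acta1b (0.13, SE 0.05) and the glycolytic gene pgam2 (0.15, SE 0.06), and the peroxiredoxin genes prdx1 (0.18, SE 0.06) and prdx6 (0.14, SE 0.06). Quantile normalization ended the call of the ribosomal protein (median 0.01, adjusted p = 0.456), oxidative phosphorylation (0.02, 0.345), lens (0.04, 0.108), skeletal muscle (-0.01, 0.230) and oxidative stress lists (0.01, 0.456). The skeletal muscle list did not pass with the replicate number as a block (camera adjusted p = 0.0907). Nor did it pass without control pool 2 (median 0.06, adjusted p = 0.0824), control pool 3 (0.06, 0.0537), control pool 4 (0.06, 0.0848), TCE pool 2 (0.03, 0.284) or TCE pool 3 (0.05, 0.113). The oxidative stress list did not pass with the replicate number as a block (0.05, 0.0539) or with normexp background correction (0.04, 0.0644), nor without control pool 1 (0.02, 0.184), TCE pool 1 (0.05, 0.0682) or TCE pool 3 (0.02, 0.395).

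Photoreceptor and retina genes stood lower in TCE, with 38 of 47 members lower (median -0.15; camera adjusted p = 0.000536, and adjusted p = 0.675 with an estimated correlation). The call ended without TCE pool 1 (median -0.04, adjusted p = 0.230) and without control pool 4 (-0.05, 0.122). The arrestin gene saga was at -0.34 (SE 0.10), while nr2e3, a nuclear receptor gene of photoreceptors, was at 0.19 (SE 0.07). In the hatching gland list, he1.1 and he1.2, which encode hatching enzymes, differed by -0.93 (SE 0.26) and -0.89 (SE 0.25). Within slide 1 they differed by -0.29 and -0.27, and within slide 2 by -1.57 and -1.50. Across pools they varied almost in parallel, lying at -0.88 and -0.30 in control pool 4 and at -2.74 and -2.04 in TCE pool 4. These hatching enzyme genes are therefore not independent measurements. Together with ctslb they passed when adjusted over the list alone (limma adjusted p = 0.0180, 0.0180 and 0.00139), which does not allow for the 34 lists so adjusted. The median of its 12 members was -0.03, 7 of them lower (camera adjusted p = 0.0248, and adjusted p = 0.659 with an estimated correlation). It was 0.0008 after normexp background correction, -0.01 with median centring and -0.02 without TCE pool 3. The hatching gland call ended with the replicate number as a block (camera adjusted p = 0.0828), without control pool 4 (0.0954) and without TCE pool 4 (0.148). Both hatching enzyme genes also belong to the epidermis list, in which 28 of 38 members were lower (median -0.05; camera adjusted p = 0.00501, and adjusted p = 0.660 with an estimated correlation). The epidermis call ended with the brightest probe per gene (median -0.01, adjusted p = 0.346), without control pool 4 (-0.05, 0.0848) and without TCE pool 4 (-0.01, 0.482), and the median ranged from -0.08 to -0.01 without 1 array. The epidermis median was -0.10 after quantile normalization (camera adjusted p = 4.34e-08) and -0.03 with median centring (camera adjusted p = 0.0172). Hypoxia response genes were lower in 15 of 21 cases (median -0.06; camera adjusted p = 0.0192, and adjusted p = 0.659 with an estimated correlation), with igfbp1a, an insulin-like growth factor binding protein gene, at -0.36 (SE 0.11) and egln3, an oxygen-sensing prolyl hydroxylase gene, at -0.28 (SE 0.10). The hypoxia call ended with the brightest probe per gene (median -0.03, adjusted p = 0.247) and without control pool 4 (-0.04, 0.105), TCE pool 2 (-0.04, 0.0926) or TCE pool 4 (-0.04, 0.0913). Without TCE pool 1 it held at a median of -0.03. The array score of the hypoxia list was lower in 4 of 4 pairs, as was that of the hatching gland list (exact permutation test, two-sided, p = 0.0286 for each, and 0.324 adjusted over the lists). Some of these pairs hardly differed. For pools 3 the hypoxia score was 0.024 in control and 0.015 in TCE, and for pools 1 the hatching gland score was -0.009 and -0.011. Circadian clock genes were lower in 26 of 33 cases (median -0.07; camera adjusted p = 0.00811, and adjusted p = 0.659 with an estimated correlation), among them cry2 (-0.19, SE 0.06) and bhlhe40 (-0.17, SE 0.06). Without TCE pool 1 (median -0.04, adjusted p = 0.0853) or control pool 4 (-0.04, 0.150) the clock list did not pass. Neuronal genes were lower in 25 of 35 cases (median -0.04; camera adjusted p = 0.0368, and adjusted p = 0.660 with an estimated correlation), with slc17a7a, a vesicular glutamate transporter gene, at -0.28 (SE 0.11). The neuron list did not pass with median centring (median -0.02, adjusted p = 0.108), the brightest probe per gene (-0.004, 0.346) or the authors' value table (-0.03, 0.0751). Nor did it pass without TCE pool 1 (-0.03, 0.0692), TCE pool 3 (-0.05, 0.111), TCE pool 4 (-0.03, 0.223), control pool 2 (-0.03, 0.0573) or control pool 4 (-0.03, 0.150), and without TCE pool 2 its median was -0.07.

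**Figure D2:**
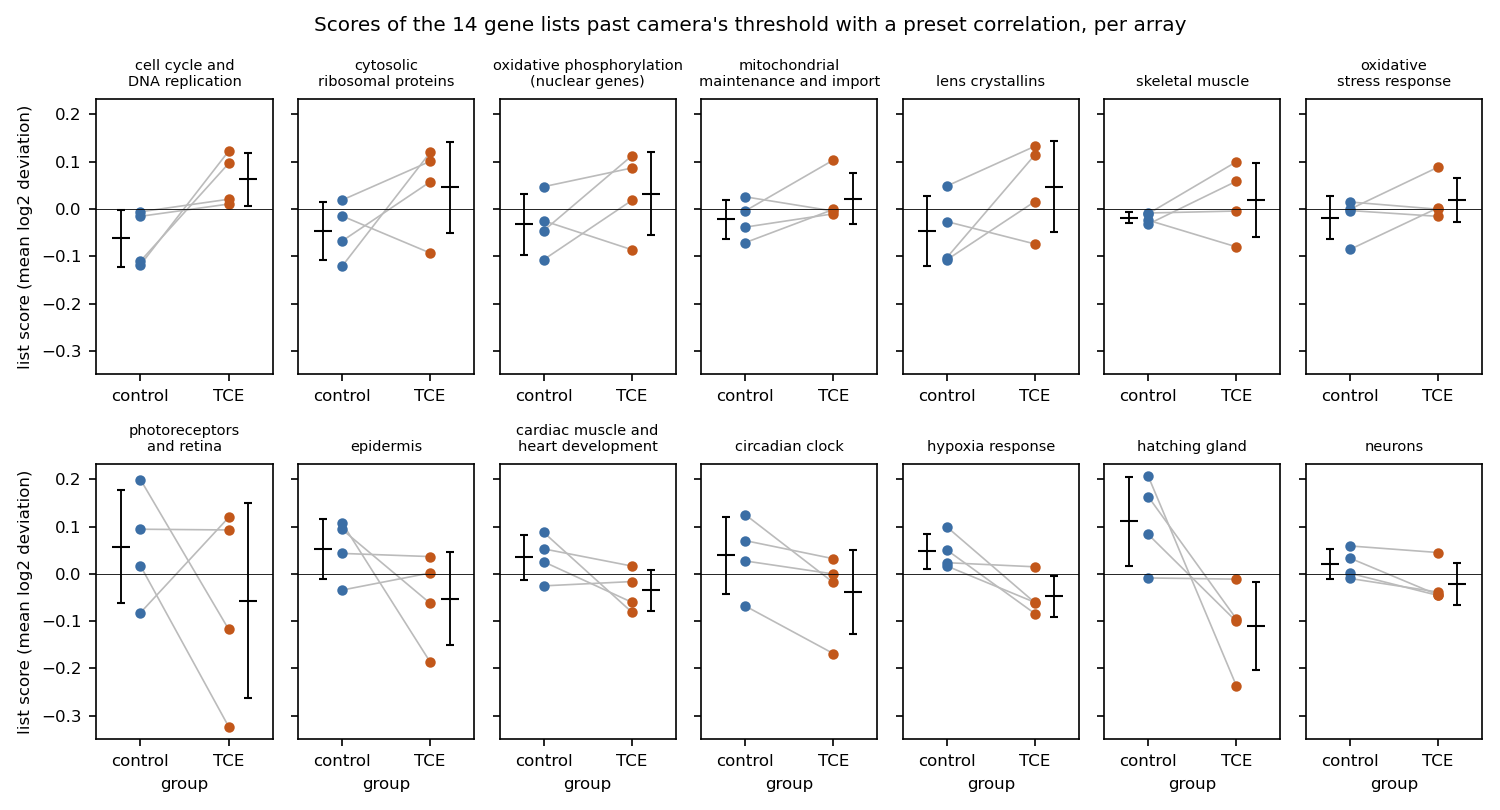
Score of each gene list (vertical axis, mean log2 deviation of the measured members from their mean over the 8 arrays) in control and TCE pools (horizontal axis) for the 14 lists past camera's threshold, higher lists in the upper row; points are arrays, grey lines join pools with the same replicate number, and black bars are mean and SD (n = 4). The groups do not overlap for cell cycle and DNA replication, overlap for ribosomal proteins and photoreceptors, and the higher skeletal muscle median turned to -0.01 after quantile normalization.

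In all, 14 of 34 fixed lists passed camera with a preset inter-gene correlation of 0.01, 7 higher and 7 lower in TCE. With an estimated correlation 0 lists passed, and fry, which tests whether a list's genes move one way on balance, called 0 as well (smallest adjusted p = 0.393). The power of either test was not measured, so these counts do not show that no list shifted. The array scores of 11 of the 14 lists had an exact permutation p (two-sided) between 0.114 and 0.429, of which 2 lay in the called direction in 4 of 4 pairs, 8 in 3 and 1 in 2. Among random lists matched on signal, the medians of 11 of the 14 lay at percentiles of at most 0.75 or at least 98.4, while hatching gland lay at 15.1, skeletal muscle at 82.9 and oxidative stress at 89.5. Random lists of unrelated genes lack the correlation within real ones (estimated at 0.62 for ribosomal proteins and 0.48 for photoreceptors). Extreme percentiles therefore do not exclude variation between pools that a list's genes share. For change in either direction fry called 6 lists: leukocytes, hatching gland, cell cycle, mitochondrial maintenance, apoptosis, and lipid and glucose metabolism. With the replicate number as a block 11 lists passed, all among the 14, and skeletal muscle (adjusted p = 0.0907), hatching gland (0.0828) and oxidative stress (0.0539) did not. With the slide as a block 14 passed. Within slide 1 alone 7 lists passed, all among the 14, and within slide 2 alone 10, of which 8 were among the 14. The 14 lists kept their direction within each slide. The cell cycle list had a median of 0.15 within slide 1 and 0.11 within slide 2, the ribosomal protein list 0.17 and 0.03, the lens list 0.14 and 0.03, and the photoreceptor list -0.17 and -0.07. Cell cycle, ribosomal proteins, oxidative phosphorylation, mitochondrial maintenance and lens passed in 8 of 8 fits that each left out 1 array, and the other called lists in 3 to 6. The count of lists was 7 without control pool 4, 10 without TCE pool 1 and 10 without TCE pool 4.

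The other lists did not pass. Markers of tissues that a whole larva holds gave camera adjusted p of 0.0871 for cartilage and bone (16 of 26 lower), 0.116 for intestine (15 of 26 lower), 0.126 for kidney (15 of 24 lower) and 0.432 for pigment cells (17 of 25 higher). Those of organs and blood were 0.433 for leukocytes (23 of 36 lower), 0.463 for exocrine pancreas (13 of 18 lower) and 0.476 for liver (16 of 31 lower). They were 0.508 for glia and myelin (16 of 26 lower), 0.758 for yolk (12 of 21 higher), 0.758 for erythrocytes (15 of 28 lower) and 0.948 for ionocytes (9 of 18 lower). Xenobiotic metabolism genes, which include the enzymes that act on foreign compounds, divided into 30 higher and 29 lower (camera adjusted p = 0.732), with cyp3a65, a cytochrome P450 gene, at -0.41 (SE 0.11) and the glutathione transferase gene gsta.2 at 0.21 (SE 0.08). Lipid and glucose metabolism genes divided into 34 higher and 37 lower (camera adjusted p = 0.346), with the gluconeogenic gene pck1 at -0.43 (SE 0.12) and the desaturase gene scdb at -0.35 (SE 0.08). The remaining lists were extracellular matrix and cell adhesion (26 of 43 lower; 0.0722), with the laminin gene lama2 at -0.48 (SE 0.12), and apoptosis and p53 targets (17 of 29 lower; 0.104). They also included heat shock and unfolded protein response (28 of 41 higher; 0.116), with ddit3 at -0.26 (SE 0.08), and DNA methylation and one-carbon metabolism (17 of 29 higher; 0.475). In the yolk and erythrocyte lists the medians, 0.05 and -0.02, had the opposite sign of the means, -0.0039 and 0.0004. The xenobiotic median of 0.004 and the calcium handling and ionocyte medians lay opposite to the direction of their tests.

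Members of these tissue lists with the smallest p were as follows. Transthyretin (ttr), a thyroid hormone carrier made in the liver, stood at -0.62 (SE 0.16) and the urate oxidase gene uox at -0.23 (SE 0.10), or -0.15 without control pool 4. The leukocyte genes rag2, of antigen receptor rearrangement, and spi1b, a myeloid transcription factor gene, lay at 0.52 (SE 0.16) and -0.27 (SE 0.09). The cartilage collagen gene col11a2 was at -0.21 (SE 0.07) and the hedgehog gene ihha at -0.16 (SE 0.07). The glial genes glulb and fabp7b were at -0.15 (SE 0.05) and 0.21 (SE 0.09), and the purine synthesis gene paics at -0.24 (SE 0.07). The intestinal peptidase gene anpepb.1 was at -0.28 (SE 0.14), at -0.16 without TCE pool 1, at -0.18 without control pool 4 and at 0.29 when outlier-marked spots were kept. In kidney the transcription factor genes hnf1bb and emx1 were at -0.32 (SE 0.17) and -0.13 (SE 0.07), and in ionocytes the sodium pump genes atp1a1a.2 and atp1b1b at 0.13 (SE 0.07) and -0.11 (SE 0.07). Without TCE pool 2 hnf1bb was at -0.21, with normexp background correction at -0.05, and with the brightest probe or the filter on all 8 arrays at -0.07, and without TCE pool 1 atp1a1a.2 was at 0.06. The pancreatic amylase gene amy2a was at -0.31 (SE 0.20), the erythrocyte list's rhag and ucp3 at -0.11 (SE 0.06) and -0.69 (SE 0.33), and the yolk list's afp4 at 0.21 (SE 0.09). For amy2a the difference was -0.16 without TCE pool 1 and -0.17 without control pool 4, and for ucp3 it was -0.46 without TCE pool 2 and -1.07 without TCE pool 3. Among pathway genes, igfbp1b was at -0.30 (SE 0.08), the apoptosis genes baxa and mcl1b at -0.17 (SE 0.06) and -0.18 (SE 0.07), the brightest probe of baxa at 0.04, and ahcyl2b and uhrf1 of the methylation list at -0.24 (SE 0.10) and 0.16 (SE 0.07). None of these genes passed the test across all genes.

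The authors' deposited table lists 851 probes, 383 higher and 468 lower in TCE. Over all listed probes the log2 change ranged from -3.18 to 3.47. The entries named here are only ones whose symbol matches a measured gene. On the higher side they are led by probes of sel1l (log2 change 1.09 in the authors' deposited table), urad (1.06) and rpl35 (1.01). On the lower side they are led by slc12a3 (-1.27), pla2g3 (-1.27) and nxpe3 (-1.11). Further entries of the authors' deposited table were lrrc59 (0.93), tmem115 (0.92) and tmem65 (-1.03). Recomputed here, the listed probes of sel1l, lrrc59, tmem115 and nxpe3 gave 1.08, 0.93, 0.91 and -1.12, while those of urad, rpl35, slc12a3, pla2g3 and tmem65 were above background on 0 to 2 arrays and were not tested. The gene means given next hold the listed probe in 2 of these 9 cases, sel1l and nxpe3, and in the other 7 rest on other probes. Those 2 means were 0.26 (SE 0.08) for sel1l, whose 5 probes ranged from -0.14 to 1.08, and -0.31 (SE 0.16) for nxpe3, whose brightest probe was at 0.07. From other probes than the listed ones, the means were 0.03 (SE 0.12) for urad, 0.15 (SE 0.06) for rpl35, 0.10 (SE 0.09) for lrrc59 and 0.05 (SE 0.08) for tmem115. They were -0.27 (SE 0.16) for slc12a3, -0.17 (SE 0.08) for tmem65 and 0.29 (SE 0.24) for pla2g3, whose tested probe was well above background in 2 of 4 control pools. Leaving out 1 array moved 6 of these 9 means by over 1.5 times. Without control pool 1 nxpe3 was at -0.18, without TCE pool 1 slc12a3 at -0.14 and without control pool 2 pla2g3 at 0.44. For lrrc59 it was 0.04 without control pool 1, 0.07 without TCE pool 1, 0.16 without control pool 2 and 0.17 without TCE pool 4. For tmem115 it was -0.001 and 0.09 without control pools 2 and 3, and 0.10 and 0.02 without TCE pools 2 and 3, and each of the 8 arrays moved urad (-0.08 to 0.12). Of the listed probes 88 carry a symbol there, and 13 share the symbol BC051665, all 13 lower.

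The 851 probes are those with an unadjusted p under 0.05 in an unpaired test with equal variances on the deposited value table and at least 1.5-fold change: the same criteria returned 851 probes, all 851 in the authors' deposited table. In those values 6845 of 128291 probes had a p under 0.05, and the smallest Benjamini-Hochberg adjusted p was 0.186. Of the listed probes 560 (65.8%) were well above background on fewer than 4 arrays, against 30.9% of all probes, and 306 (35.96%) on no array, against 20.8%. Of the 291 listed probes that were tested here, 0 passed after adjustment in limma. All 291 had an unadjusted p under 0.05, which their selection on the same arrays favours.

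**Figure D3:**
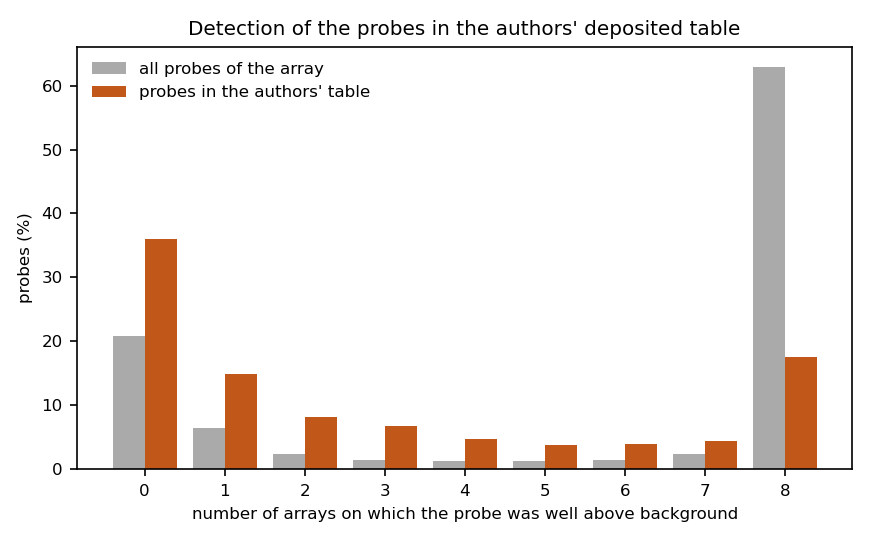
Percentage of probes (vertical axis) by the number of the 8 arrays on which they were well above background (horizontal axis), for all 128291 probes in grey and for the 851 probes of the authors' deposited table in orange. Of all probes 62.9% were detected on 8 arrays, against 17.5% of the listed probes.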

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

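In this part the tests of a signal intensity trend, of variation shared by the genes of a list, of array position, of cross-hybridization and of hatching genes by slide were chosen after the result was seen.

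In 18 of 250 groups of 4 pools, 1 pool lay far from the others: its gap to the nearest other pool, divided by the group's range, was over Dixon's critical value for 4 samples. Chance flags about 1 in 20 groups, or 12.5 here. Among control pools these were calm2a (0.935) and pola2 (0.919) for pool 4, pgam2 (0.846) for pool 3 and pla2g3 (0.851) for pool 2. Among TCE pools they were fabp4b (0.847) and atp1a1a.2 (0.837) for pool 1, hnf1bb (0.862) and chsy1 (0.921) for pool 2, igfbp1a (0.981), rag2 (0.910) and dll4 (0.902) for pool 3 and rps27.1 (0.852) for pool 4. The list scores set apart were those of cartilage and bone (0.918) and neurons (0.922) for TCE pool 2, and of heat shock and unfolded protein response (0.861) and mitochondrial maintenance (0.919) for TCE pool 3. Of the quality measures, the share of probes above background set control pool 3 apart (0.898) and the share of outlier-marked spots control pool 1 (0.878). TCE pool 3 stood apart in 5 of the 18 groups and TCE pool 2 in 4.

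Chance was examined with the 35 ways of splitting the 8 arrays into 4 and 4. For genes and for probes past adjusted p 0.05 the real count was 0, which every split must reach, so the comparison decides nothing there, and the highest other counts, from the split by slide, were 1597 genes and 1637 probes in limma. For genes with an unadjusted p under 0.05, 9 of 35 splits gave as many as the real 3079, so chance could not be excluded. The highest was 8739, from the split by slide, which points to a structure of the arrays by slide; the count with the slide as a block was 4011. The real split parts each pair of pools with the same number, and among the 8 splits that do so its 3079 was the largest, the next being 2263, while the other splits keep some pairs together.

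The first pattern is that 14 of 34 lists passed camera. As many lists came from 3 of 35 splits, the highest other count being 15, and from 2 of the 8 splits that part each pair, so chance could not be excluded. A trend with signal intensity is argued against for the cell cycle list, whose median was 0.13 after quantile normalization. Of the lower lists 7 of 7 then passed in the same direction. The trend raised bright genes in TCE (median of the brightest 10% of targets 0.04, and -0.002 after quantile normalization). Its removal could only push bright lists lower, so for lower lists of bright genes this result decides nothing. The clock list, whose median member lay at signal percentile 32.1, kept a median of -0.06. Of the higher lists 2 of 7 passed, so the trend may account for the other 5, although this normalization would also remove a true shift shared by bright genes. Variation between pools that a list's genes share stays open, as does a response to TCE: 3 of the 14 lists had an exact permutation p under 0.05 for their array scores, simulated noise of that kind gave camera 3 to 20 calls, and array position cannot be told apart from treatment, as 0 positions held both groups.

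The second pattern is the authors' deposited table of 851 probes. The same criteria returned as many probes in 24 of 35 splits, the highest being 2727 from the split by slide, and in 3 of the 8 splits that part each pair (highest other 1218), so chance could not be excluded. Probes near background may supply most such lists: among the probes picked by the other splits a median of 73.1% were dim (39.6% to 89.6%), against 65.8% in the real split. A response to TCE in part of these probes stays open.

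The third pattern is the lower level of hatching gland protease genes. Cross-hybridization among the tandem cathepsin L copies stays open: he1.2, from another protease family, differed by -0.89, but it was picked as lower and overlapped between groups (exact permutation test, two-sided, p = 0.0571; lower in 3 of 4 pairs). Variation in hatching progress between pools stays open for the hatching enzyme genes: he1.1, not a measurement independent of he1.2, overlapped likewise. For he1.1 the span of 0.92 among the control pools lay mostly between slides. Its difference was -0.29 within slide 1, where TCE pools lay 0.70 apart, and -1.57 within slide 2, where they lay 0.58 apart and with 2 pools per group neither reading is excluded. For ctslb the groups did not overlap (exact permutation test, two-sided, p = 0.0286, the smallest that 70 unpaired assignments can give), but it was picked as lower on the same arrays, which favours that outcome. Hatching state is not given in the sources used here, so that an effect of TCE on hatching was not tested apart from it.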

How the results depend on the processing

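A refit to named genes alone and the comparisons within each slide were chosen after the data were seen. Limma called 0 genes with all arrays and in every alternative except without control pool 1, so that leaving out 1 array gave 0 to 1. The count at an unadjusted p under 0.05 was 3079, against 4619 with the replicate block and 2533 to 3527 without 1 array. It was 1130 of 12806 in the refit to named genes alone (smallest adjusted p = 0.0825 in limma), against 820 of the same genes in the fit to all. The log2 differences are the same in both fits. The variance that limma shares across genes was estimated anew, and the adjustment ran over the named genes alone. Probes called were 0, and 4 with the replicate block. Lists past the threshold were 14, against 11 with the replicate block, 7 within slide 1 and 10 within slide 2, of which 8 were among the 14. They were 0 with an estimated correlation, 0 with fry and 7 to 15 without 1 array, the 7 without control pool 4. With quantile normalization 12 passed, 9 of them among the 14, and with the brightest probe per gene 14, 10 of them among the 14, the heart, epidermis, hypoxia and neuron lists being lost.

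A list's direction is that of its set test, and 11 lists turned, of which skeletal muscle alone was among the 14. List medians where the test turned were as follows. With quantile normalization they were -0.0111 for skeletal muscle and 0.00894 for yolk. For ionocytes they were 0.0226 with median centring, 0.0372 with normexp, -0.000982 with no filter, 0.00742 with the brightest probe, 0.00819 with the authors' value table and 0.0187 within slide 2. With no filter they were 0.0149 for calcium handling and -0.0153 for erythrocytes, and with the brightest probe 0.0297 for extracellular matrix. Within slide 1 they were 0.0279 for DNA methylation, 0.00928 for erythrocytes, -0.0656 for exocrine pancreas, -0.0167 for vascular endothelium and 0.0129 for xenobiotic metabolism. Within slide 2 they were 0.0334 for calcium handling and -0.0069 for yolk. Without 1 array the medians ranged from -0.00947 to 0.0308 for ionocytes, -0.0409 to 0.0457 for calcium handling, -0.245 to 0.116 for exocrine pancreas, 0.0135 to 0.0411 for yolk, -0.0252 to 0.0224 for erythrocytes, -0.0414 to 0.0264 for xenobiotic metabolism and -0.0915 to 0.0153 for leukocytes.

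Of 87 named genes 15 moved by over 1.5 times without 1 array and 39 under another alternative, and 7 changed sign. With normexp igfbp6b was at -0.40, ahcyl2b at -0.15, myh7 and bhlhe40 at -0.08, lama2 at -0.27, sel1l at 0.15, rag2 at 0.29, spi1b at -0.17, saga at -0.23, angpt2b at 0.14, urad at 0.10, slc12a3 at -0.12, pla2g3 at 0.18 and nxpe3 at -0.15. With the brightest probe abcc5 was at -0.70, ahcyl2b at -0.08, bhlhe40 at -0.10, ucp3 at -0.44, amy2a at -0.18, atp1b1b at -0.03, emx1 at -0.23, paics at -0.11, acta1b at 0.08 and urad at 0.06. With quantile normalization calm2a was at 0.10, rpl35 and cycsb at 0.07, rps27.1, crygm2d1 and atp5mc3a at 0.06, acta1b at 0.05, pgam2 at 0.09 and afp4 at 0.12. Urad was at 0.06 with median centring, gch2 at 0.16 within slide 2 and tmem115 at 0.008 with array weights and 0.02 with outlier-marked spots kept. With no filter nxpe3 was at -0.15 and chsy1 at 0.57, and within slides 1 and 2 chsy1 was at 1.69 and 0.19. With no filter pla2g3 was at -0.43, and with the brightest probe baxa was at 0.0443 and nxpe3 at 0.0701. The intestinal gene anpepb.1 was at 0.24 in the authors' value table and 0.29 with outlier-marked spots kept, where ush1c was at -0.20. Without 1 array urad ranged from -0.0760 to 0.116 and tmem115 from -0.0015 to 0.10. Apart from the smaller number of genes or arrays in some alternatives, the cause was not tested. Scan date followed the slide and was not run. Signal over background limits what can be said of dim probes, 30.9% of all probes being above background on fewer than 4 arrays.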

Other observations

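The gene groups and the immediate-early test in this part were chosen after values of some of their members were seen.

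Genes of the cathepsin L cluster that holds ctslb stood lower together. Of 21 annotated genes in the cluster 6 were measured, and all 6 were lower in TCE at an unadjusted p under 0.05, with a median log2 difference of -0.65 (-0.69 to -0.41), and lower under each of 5 scalings. Their mean was lower in 4 of 4 pairs (exact permutation test, two-sided, p = 0.0286, the smallest that 70 unpaired assignments can give). The cluster was looked at because ctslb, one of the 6, had been picked as lower on these arrays, so this p in part restates that choice. Of the 20 genes flanking the cluster 12 were lower, with a median of -0.02, 0 of them lower and 2 higher at an unadjusted p under 0.05. Probes of such similar copies can bind each other's transcripts, so the 6 genes are not independent measurements.

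Protocadherin genes, which encode adhesion proteins, also stood on the lower side. They were taken by the start of the symbol, pcdh2 or pcdh1. These sets, pcdh1 above all, can therefore also hold protocadherins from outside the gene clusters. Of the pcdh2 genes 14 of 14 were lower (13 of 14 in the authors' value table), 5 at an unadjusted p under 0.05, with a median of -0.12 (exact permutation test, two-sided, p = 0.0857; lower in 3 of 4 pairs). With normexp background correction their median was -0.08. Whether probes of these related genes bind each other's transcripts was not tested. The 14 genes are therefore not taken as independent measurements. Of the pcdh1 genes 18 of 24 were lower (16 of 24 with median centring and with normexp), 0 at an unadjusted p under 0.05 in limma (exact permutation test, two-sided, p = 0.171; lower in 3 of 4 pairs). Among hypoxia response genes beyond those named earlier, bnip3 was at -0.35 (SE 0.14) and the glucose transporter gene slc2a1a at -0.51 (SE 0.22), and lepa was not a member of that list.

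A hypothesis raised by fosab and ier2a is that the immediate-early response, in which such genes are induced within minutes of a stimulus, may have been lower in the TCE pools. It was tested on a list of 45 genes written for the purpose, without 5 whose values had been seen. The rest were measured on the same arrays and varied together (estimated correlation 0.13), and some belong to fixed lists tested earlier. A difference between pools that lowered fosab could lower them too, so they are not an independent test. Of the remaining 31 measured genes 29 were lower, with a median of -0.11 (camera p = 2.48e-08, p = 0.0271 with an estimated correlation, fry p = 0.0181). Among them were socs3a (-0.40, SE 0.11), btg2 (-0.20, SE 0.06) and egr1 (-0.69, SE 0.39), and 0 genes passed in limma when adjusted over the list alone, 6 having an unadjusted p under 0.05. The array score was lower in 4 of 4 pairs (exact permutation test, two-sided, p = 0.0286, the smallest that 70 unpaired assignments can give), and medians without 1 array lay between -0.15 and -0.07. The result is consistent with the hypothesis, but these genes also respond to handling, and whether pools were handled alike at collection is not given in the sources used here.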
